A study of Astyanax mexicanus with 12 samples.

How the data were processed

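Bulk RNA was sequenced from the right ovaries of Astyanax mexicanus females, a fish with river-dwelling surface populations and blind cave populations, here surface fish and cavefish of the Tinaja population. The labels put 12 libraries into 4 groups of 3: control and starved surface fish, and control and starved Tinaja cavefish, all aged about 660 days after fertilisation. How long the starved fish went without food is not given in the sources used here. Nothing in the labels says more about how the replicates of a group relate to each other than that they are separate samples, so p-values measure the spread between these samples.

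Per the labels' protocols, total RNA was extracted with a phenol-based reagent, purified on columns with DNase digestion, depleted of ribosomal RNA and made into directional libraries, which were read on a Singular Genomics instrument. The authors deposited a table of raw counts, that is whole reads per gene and library, with 27420 genes. The submitters' processing notes name STAR 2.7.10b and RSEM, without the role of either. The genome build, the annotation and the strand setting used for counting are not given in the sources used here, so overlapping and antisense genes, and near-identical copies of a gene, are treated as uncertain. The authors also deposited a scaled signal table with 14627 genes, with column sums of 953330 to 1097178. Its values equal the CPM (read counts scaled to a common library size) that edgeR gives with trimmed mean of M values (TMM) factors on the genes kept by edgeR's default expression filter, with a largest relative difference of 4.97e-15. In that signal table, 100% of the deposited values came out as whole reads within 0.001, and the count test on the recovered reads called 466 genes for starvation in surface fish, as many as the test on the deposited counts.

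The last 4 entries of the count table name no gene and were left out of library sizes and tests. They hold unmapped reads (7.28% to 10.1% of all reads per library), reads mapped to several places (9.91% to 16.8%), reads outside any annotated gene (14.1% to 17.9%) and ambiguous reads (0.276% to 0.368%). Between 5949160 and 10198900 reads per library were assigned to genes. Symbols were taken from the count table, which pairs 16752 of the gene identifiers with a symbol and leaves 10668 without.

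Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 on the 4 groups (14627 genes kept), TMM factors, a robust quasi-likelihood fit of all 12 libraries with 1 mean per group, and quasi-likelihood F tests with Benjamini-Hochberg adjustment over all genes tested. An adjusted p under 0.05 is called. The biological coefficient of variation was 0.191 with 8 residual degrees of freedom, and the median standard error of a log2 fold change was 0.172 to 0.173, or 0.244 for the difference between the populations' responses. For a gene, the standard error (SE) given is the size of its log2 value divided by the square root of F, an approximation. The 5 comparisons were starved against control in each population, the difference between those 2 responses, and Tinaja against surface fish in each feeding state. Levels are TMM-scaled CPM, as mean ± SD of 3 libraries. For a gene without a read in a group, the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts it is a ratio with a 95% counting interval; these cover counting error only. In each library 3 counts equal 0.323 to 0.491 CPM.

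Before the data were examined, 37 gene lists were fixed, covering the oocyte and its follicle, steroid hormones, metabolism and nutrient signalling, stress, the cell cycle, immunity, the clock and markers of other cell types. Of these, 36 held at least 5 tested genes. The lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 36 lists. With a correlation estimated per list, 0 lists were called in any comparison, against 6, 2, 8, 2 and 5 lists at the preset correlation and 12, 0, 2, 6 and 18 by the rotation test fry, in the order of the comparisons above. The pattern for ribosomal protein symbols also takes in RPS6KL1, a kinase-like gene that is no ribosomal protein; without it the numbers of lists called were the same.

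The genes named in the text follow a rule fixed before the data were examined. It takes, per comparison, the 6 largest rises and the 6 largest falls among called genes that carry a real name, average at least 1 CPM over the libraries compared and do not overlap between the groups (without that last condition for the difference between responses). It adds up to 4 called genes of smallest adjusted p from each list with at least 3 calls in 1 direction or a camera call, and 18 key genes whatever their result. Where the lists name more than 18 genes, 2 examples per list are given. Genes known only by an identifier fall outside the rule and were named after their values were seen.

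The fit was tested on simulated counts drawn from the real library sizes and the real means, pooled over all 12 libraries. The spread of each gene was the one edgeR estimated, so the shares of false calls may favour edgeR. The 200 changed genes were taken from the better counted genes only, so recovery of genes with few reads was not measured. Genes were drawn independently, without the difference between the populations or other structure of the samples, so shares in the real data may differ. For starvation in surface fish, edgeR recovered 32.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.4% of those changed 4-fold, over 14276 genes, and 3.01% of its calls were false. For starvation in Tinaja cavefish the shares were 37.3%, 61.2% and 89.4% over 14281 genes, with 3.85% false. In the same simulations 17.1% and 16.2% of the calls of DESeq2 were false, and 2.29% and 0.813% of those of limma voom.

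Alternatives fixed before the data were examined were relative log expression and upper-quartile factors, DESeq2 1.42.0, limma voom with sample weights, no low-count filter, a filter of 10 CPM in 3 libraries, the replicate number as a block, a fit of only the groups compared, a minimum change of 2-fold, and leaving out each library in turn. Thinning every library to the reads of the smallest, the recovered reads and the ribosomal list without RPS6KL1 were added after seeing the data. No pair of libraries of the same group agreed within sampling noise, which argues against a library that was read again. It cannot tell whether the libraries came from different fish. Each was counted as 1 replicate because the labels give separate samples.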

Results

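Gene expression was measured by RNA sequencing in 12 ovaries of adult Astyanax mexicanus females: 3 control and 3 starved surface fish, and 3 control and 3 starved Tinaja cavefish. Reads assigned to genes ranged from 7152580 to 10198900 per library in surface fish and from 5949160 to 7973060 in Tinaja cavefish, and 14627 genes were expressed highly enough to be tested. The first principal component held 68.8% of the variance of the 2000 most variable genes and parted the populations. Its scores were 53.0 to 60.8 in surface fish and -59.4 to -54.7 in Tinaja cavefish. The second held 5.72% and parted control surface fish (10.6 to 12.2) from starved surface fish (-14.8 to -6.89). In Tinaja cavefish it did not follow feeding. There, control 1 and starved 2 and 3 scored 26.7, 23.4 and 7.60, and control 2 and 3 and starved 1 scored -22.1, -16.0 and -20.9. The third component held 4.73% and did not follow feeding in surface fish. Surface control 2 and 3 scored 27.1 and 27.8 on it. Surface control 1, at -10.2, lay with the starved surface fish (-20.2 to -10.9). Correlations of log2 CPM across genes between pairs of libraries were 0.961 to 0.973 within groups and 0.870 to 0.889 between populations.

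**Figure D1:**
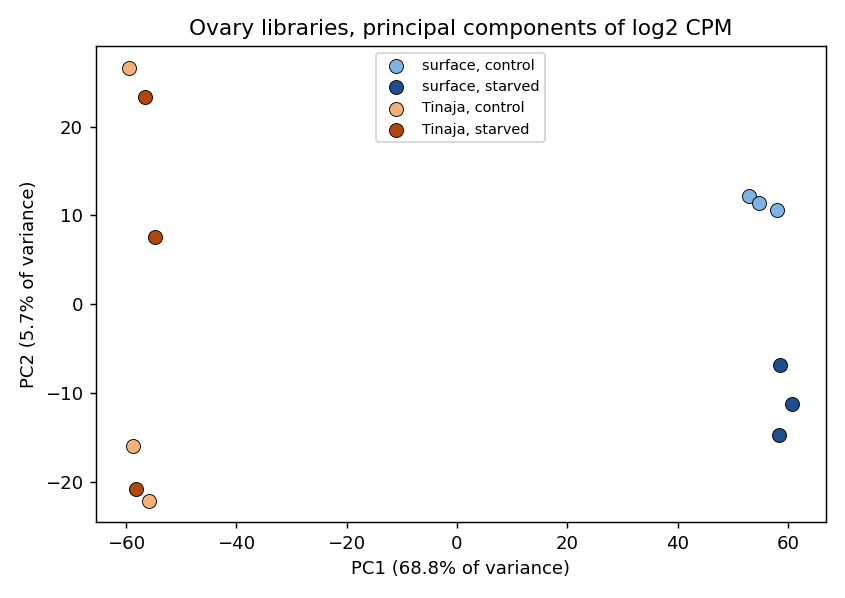
Principal components of log2 CPM of the 12 ovary libraries, 1 point per library, with the share of variance on each axis. The first component separates surface fish from Tinaja cavefish, and the second separates control from starved surface fish but splits the Tinaja libraries across their groups.

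In surface fish, genes of the egg coat, the ribosome and the cell cycle were among those that rose with starvation, and the receptor genes lepr, pgr and lhcgr and the clock gene clockb among those that fell. The ribosomal protein gene rpl3 rose from 832 ± 47.1 to 1371 ± 93.8 CPM (n = 3 each) and the egg coat gene zp3c from 409 ± 31.1 to 662 ± 130. The gene ccnb2, a cyclin of cell division, rose from 1662 ± 203 to 2427 ± 139. The leptin receptor gene lepr fell from 21.8 ± 2.83 to 11.1 ± 1.45 CPM and the progesterone receptor gene pgr from 11.5 ± 1.54 to 3.89 ± 1.53. The gene of the luteinizing hormone receptor, lhcgr, fell from 4.85 ± 0.654 to 1.34 ± 0.864, a log2 change of -1.87 (-2.50 without starved 1). The clock transcription factor gene clockb fell from 69.9 ± 11.4 to 43.1 ± 5.14 CPM. Adjusted p-values of the edgeR quasi-likelihood test were 0.00624 for rpl3, 0.0255 for zp3c, lepr and clockb, 0.0358 for ccnb2, 0.0488 for pgr and 0.0491 for lhcgr.

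Under the naming rule, which takes genes with a real name that average at least 1 CPM and do not overlap, the largest rises included those of SHANK3, a scaffold protein of synapses (0.675 ± 0.460 to 10.4 ± 2.46 CPM), MYOM2, a protein of the muscle sarcomere (2.67 ± 2.49 to 25.8 ± 7.76), and PM20D2 (0.176 ± 0.0827 to 2.87 ± 1.04). The neurotrophic factor gene cdnf rose from 0.241 ± 0.418 to 3.69 ± 1.09 CPM, with reads in control 1 alone among the controls, and the organic cation transporter gene slc22a2 from 0.445 ± 0.327 to 4.43 ± 1.47. NAV2 rose from 1.46 ± 0.648 to 19.0 ± 13.9 CPM, with 195, 206 and 28 reads in the 3 starved libraries. Under the same rule the largest falls were those of the potassium channel gene kcnd3 (7.49-fold), pfkfb2a, which encodes a regulator of glycolysis (6.17 ± 2.61 to 1.06 ± 0.782 CPM), and the 5_8S_rRNA gene (5.41-fold). They were followed by PDE7A (4.59-fold), parp8 (4.11-fold) and ADAMTS7 (4.09-fold). Leaving out 1 library moved some of these folds by over 1.5 times, given here as log2 changes. Without control 1 they were 4.62 for SHANK3 (3.89 with it) and 4.38 for MYOM2 (3.25), the controls of cdnf (3.76) held 0 reads and gave no fold, and without control 3 slc22a2 had 4.03 (3.28). Without starved 3 pfkfb2a had -3.15 (-2.49) and without starved 1 PDE7A had -2.79 (-2.20). With voom cdnf had 4.77. The libraries were depleted of ribosomal RNA, so the level of the 5_8S_rRNA gene also depends on that step. A gene without a symbol, ENSAMXG00000032655, had 0 reads in all control surface fish and 98, 118 and 115 reads in the starved ones, at least 105-fold more, and was singled out after its values were seen.

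Across the fixed lists, 27 of 82 genes of the ribosomal list rose and 55 were not called. Adjusted over the list alone, 73 rose and 1 fell. The list includes RPS6KL1, a kinase-like gene that is no ribosomal protein and was not called here (adjusted p = 0.642). Among the risen, rpl6 went from 424 ± 24.6 to 604 ± 44.7 CPM and rps8a from 394 ± 13.7 to 548 ± 38.8. Of 23 oocyte genes, 6 rose and 17 were not called (15 rose adjusted over the list alone). Of these, rbpms2b, an RNA-binding protein gene of the oocyte, went from 599 ± 72.5 to 856 ± 76.4 CPM and zar1l from 823 ± 72.6 to 1178 ± 97.6. The germline gene piwil2 and bmb, which acts in fusion of the pronuclei, rose 1.22-fold and 1.23-fold. Of 9 egg coat genes, zp3c and zp2l2 (652 ± 111 to 1020 ± 106 CPM) rose, 7 were not called, and 7 rose adjusted over the list alone. Of 40 cell cycle genes, 9 rose (16 adjusted over the list alone), including ccna2, cdc20 and tpx2, and 31 were not called. Of 84 nuclear genes of oxidative phosphorylation 1 rose, ndufs3 (87.1 ± 4.26 to 113 ± 4.89 CPM), also 1 adjusted over the list alone. The median log2 change was 0.39 for the ribosomal, 0.30 for the oocyte, 0.41 for the egg coat, 0.18 for the cell cycle and 0.16 for the oxidative phosphorylation list. In that order the camera adjusted p was 5.77e-26, 1.62e-08, 0.000117, 2.62e-05 and 4.74e-09. Each of these calls was lost, at adjusted p = 0.391 with an estimated correlation.

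Of 10 granulosa cell genes tested, lhcgr fell and 9 were not called, and 5 fell adjusted over the list alone. The median log2 change was -1.56 (camera adjusted p = 0.000595). This call too was lost, at adjusted p = 0.391 with an estimated correlation. In the ovulation list 3 of 19 genes fell: pgr, lhcgr and hif1ab, a subunit of the hypoxia-inducible factor (206 ± 25.1 to 146 ± 17.8 CPM). Adjusted over the list alone 4 fell and 1 rose, and the list was not called (camera adjusted p = 0.305). In the clock list 3 of 33 genes fell, clockb, tefb (57.8 ± 1.85 to 41.8 ± 1.96 CPM) and cry2 (33.8 ± 4.64 to 23.2 ± 0.542). Adjusted over the list alone 5 fell and 1 rose, and the list was not called (camera adjusted p = 0.0762). The theca, stroma, macrophage, blood vessel and smooth muscle lists were not called (camera adjusted p of 0.0762, 0.383, 0.736, 0.801 and 0.201), and adjusted over the list alone 4 of 14 theca genes and 1 of 15 smooth muscle genes fell. The mean log2 CPM of the marker lists, starved minus control surface fish, was -1.14 ± 0.124 (SE) for granulosa cells, -0.61 ± 0.0645 for theca and steroid synthesis and -0.49 ± 0.234 for stroma. It was -0.51 ± 0.344 for smooth muscle, -0.28 ± 0.320 for macrophages and -0.22 ± 0.0939 for blood vessels. The 10 most abundant genes took 3.61% ± 0.233 of gene reads in starved and 2.84% ± 0.370 in control surface fish.

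Among the key genes that were not called, zar1 measured 655 ± 75.2 CPM in control and 935 ± 52.8 in starved surface fish (adjusted p = 0.0542) and ddx4 571 ± 30.1 and 663 ± 35.7 (0.185). The oocyte growth factor genes gdf9 and bmp15 measured 67.2 ± 1.18 and 72.3 ± 7.59 (0.523) and 133 ± 6.37 and 146 ± 17.4 (0.358). The steroid enzymes cyp17a1 and cyp19a1a measured 0.898 ± 0.584 and 0.162 ± 0.0465 CPM (0.0802) and 1.51 ± 0.373 and 0.144 ± 0.249 (0.101), near the level of 3 reads. The receptor gene fshr was at 2.15 ± 0.459 and 1.23 ± 0.375 CPM (0.396), insra at 120 ± 18.2 and 110 ± 10.1 (0.512) and cpt1aa at 10.7 ± 0.738 and 6.30 ± 2.06 (0.321). Too few reads were counted to test star, foxl2a, amh, igf1 and pck1, none of which exceeded 11 reads in any library, and lrp13 and fasn carry no entry under those symbols in the table used here.

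In total 466 genes were called in surface fish, 254 higher and 212 lower, of which 88 changed at least 2-fold (35 higher, 53 lower), and 3296 had an unadjusted p under 0.05. The count depended on single libraries: it was 540 without control 1, 30 without control 2 and 27 without control 3. It was 155 without starved 1, 181 without starved 2 and 92 without starved 3. A fit of these 6 libraries alone called 141 genes and DESeq2 1304. The 35 called genes followed through the alternatives were those named by rule and ENSAMXG00000032655. Of these, 7 lost the call without control 1, 31 without control 2, 31 without control 3, 18 without starved 1, 18 without starved 2 and 26 without starved 3, at adjusted p up to 0.163. In the fit of these 6 libraries alone 22 of 34 lost it (up to 0.101), with voom 9 (up to 0.208), with upper-quartile factors 5, with thinned libraries 5 and without the low-count filter 3. PM20D2, SHANK3 and rpl3 were called in each of these.

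**Figure D2:**
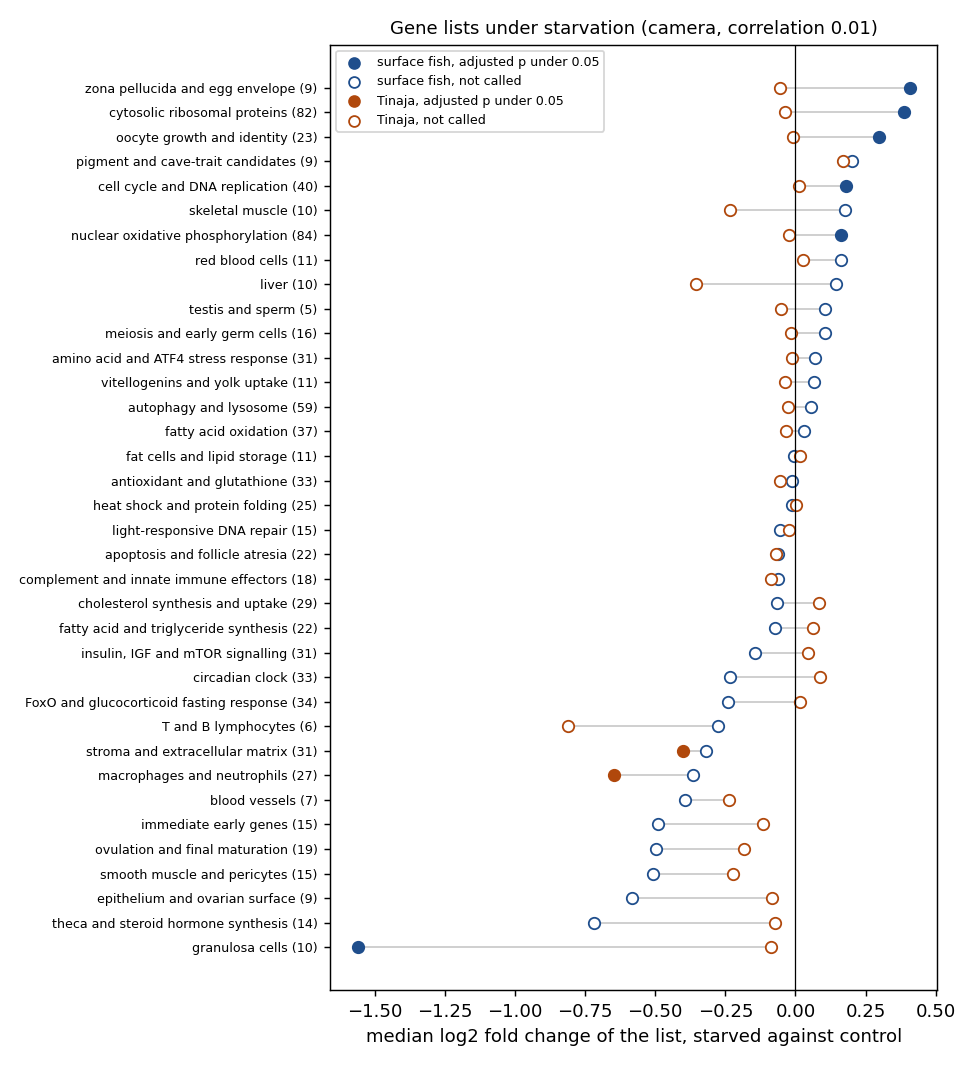
Median log2 fold change between starved and control fish for each fixed gene list with at least 5 tested genes (number in brackets), in surface fish (blue) and Tinaja cavefish (orange); filled points have a camera adjusted p under 0.05 at a preset correlation of 0.01. The surface medians run from -1.56 for granulosa cells to 0.41 for the egg coat, and the filled Tinaja points are macrophages (-0.65) and stroma (-0.40).

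In Tinaja cavefish, the starvation comparison called 3 genes, and none of the tested key genes was among them. BAHCC1, which encodes a chromatin-associated protein, rose from 48.5 ± 2.84 to 85.9 ± 12.2 CPM (adjusted p = 0.0137). A second gene with the same symbol measured 37.5 ± 10.0 and 37.5 ± 5.28 CPM, so the division of reads between the copies is uncertain. ENSAMXG00000001654 fell from 78.4 ± 5.92 to 42.5 ± 3.03 CPM (0.00219). ENSAMXG00000016415 had 73, 51 and 48 reads in the control fish and 0 in all starved ones, at least 60.9-fold fewer (0.00354). The latter pair were named after their values were seen. In control and starved Tinaja cavefish the key genes measured 13.1 ± 2.64 and 14.7 ± 6.62 CPM for lhcgr, 27.4 ± 3.78 and 26.5 ± 3.63 for lepr, and 728 ± 142 and 713 ± 80.6 for zar1. They measured 56.6 ± 4.83 and 55.0 ± 0.735 CPM for gdf9, 112 ± 3.04 and 112 ± 4.45 for bmp15 and 649 ± 95.1 and 601 ± 22.2 for ddx4. They were 4.46 ± 0.757 and 4.61 ± 1.89 CPM for cyp17a1, 1.65 ± 0.937 and 0.797 ± 0.771 for cyp19a1a, 3.30 ± 1.72 and 2.47 ± 1.03 for fshr, 130 ± 2.20 and 131 ± 4.72 for insra and 8.49 ± 4.53 and 8.25 ± 3.54 for cpt1aa. The adjusted p was 1 for each of these 11 genes.

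Of the 36 lists, camera called 2 as lower in starved Tinaja cavefish, with 0 called members in each by edgeR. The 27 macrophage and neutrophil genes had a median log2 change of -0.65 (camera adjusted p = 1.81e-05, and adjusted p = 0.315 with an estimated correlation). The 31 stroma genes had -0.40 (camera adjusted p = 0.00183, and adjusted p = 0.533 with an estimated correlation). Adjusted over the list alone, 0 genes of either list were called by edgeR, 578 of all tested genes had an unadjusted p under 0.05, and fry called 0 lists. The mean log2 CPM of the macrophage list was 2.58, 1.56 and 2.13 in the control and 0.962, 2.13 and 1.11 in the starved libraries. That of the stroma list was 4.18, 3.11 and 3.57 against 2.47, 3.63 and 3.28, and the groups overlapped for both. For both lists control 1, control 3 and starved 2 lay above the other 3 libraries. The fat cell list, at 3.79, 2.26 and 3.13 in control and 1.92, 3.60 and 2.25 in starved libraries, and the epithelium list, at 4.63, 3.38 and 3.88 and 3.12, 4.00 and 3.50, had the same 3 libraries on top. The stroma call ended without control 1 (0.398) and without starved 1 (0.949). The number of lists called was 4, 6 and 9 without control 1, 2 and 3, and 1 and 13 without starved 1 and 2. The count of called genes was 21 without control 1, 5 without control 2, 34 without starved 1 and 5 without starved 3. DESeq2 called 20 and voom 4, and a fit of these 6 libraries alone called 0 with 452 genes at an unadjusted p under 0.05. BAHCC1 lost its call without control 3 (0.0718), and ENSAMXG00000016415 with voom (0.125).

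Between the starvation responses of the populations, edgeR called 0 genes in both, where independent lists of these sizes would share 0.0174 higher and 0.0290 lower genes. DESeq2 called 2 in both, of which 1 was lower in both, and 3296 and 578 genes had an unadjusted p under 0.05. Of the 466 genes called in surface fish, 222 (47.6%) had a log2 change of the same sign in Tinaja cavefish. Their median change there, signed by the surface direction, was -0.01 on the log2 scale against 0.54 in surface fish. Across all tested genes, which are not independent replicates, the log2 changes in the 2 populations had a correlation of 0.00461.

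The test of the difference between the 2 responses called 10 genes. SHANK3, which rose in surface fish, measured 6.21 ± 0.930 and 5.13 ± 1.29 CPM in control and starved Tinaja cavefish, a difference of -4.17 ± 0.535 (SE) on the log2 scale (adjusted p = 0.0115). Without surface control 1 it was -4.90. The gene spg11, linked to lysosome function, measured 43.2 ± 3.61 and 78.9 ± 3.52 CPM in surface fish and 103 ± 4.33 and 103 ± 5.72 in Tinaja cavefish (-0.87 ± 0.111, 0.0115). BAHCC1 measured 141 ± 7.60 and 120 ± 8.69 CPM in surface fish against its rise in Tinaja cavefish (1.05 ± 0.141, 0.0129). The mitochondrial inner membrane gene letm1 measured 24.9 ± 0.967 and 14.7 ± 1.02 CPM in surface fish and 16.4 ± 0.394 and 22 ± 2.11 in Tinaja cavefish (1.19 ± 0.169, 0.0192). PM20D2 measured 12.5 ± 1.99 and 14.7 ± 1.14 CPM in Tinaja cavefish (-3.66 ± 0.522, 0.0192). None of the tested key genes was called by this test. For lepr, zar1 and lhcgr the differences were 0.92, -0.54 and 2.04 on the log2 scale (0.160, 0.220 and 0.189).

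Of the 10 genes, 3 had a higher and 7 a lower response in Tinaja cavefish, and 2264 genes had an unadjusted p under 0.05. The count was 49 without surface control 1, 16 without surface starved 1, 16 without surface starved 2, 22 without surface starved 3. It was 26 without Tinaja control 1 and 22 without Tinaja starved 1, and DESeq2 called 255. The call of letm1 ended without surface control 2 (0.0740) or 3 (0.0735), without Tinaja control 2 (0.0646) or 3 (0.0575), without Tinaja starved 3 (0.0701) and with thinned libraries (0.103). That of PM20D2 ended without surface control 3 (0.0864), without Tinaja control 2 (0.0523) or 3 (0.0575), without Tinaja starved 2 (0.0519) or 3 (0.0663), with voom (0.125) and with thinned libraries (0.0995).

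By camera, 8 lists differed in their response, with 0 called members in each by edgeR at the threshold over all genes. The ribosomal list had a median difference of -0.44 on the log2 scale (camera adjusted p = 1.98e-23; 48 genes lower adjusted over the list alone), oxidative phosphorylation -0.21 (4.28e-09; 0 genes) and oocyte -0.29 (7.63e-07; 6). It was -0.48 for the egg coat (0.000381; 6) and -0.19 for the cell cycle (0.00178; 3), where a negative value is a lower response in Tinaja cavefish. The granulosa list had 1.5 (0.00662; 0 genes), the clock list 0.28 (0.0193; 5 genes higher) and the insulin and mTOR list 0.24 (0.0204; 2). In the same order these calls were lost, at adjusted p = 0.385, 0.385, 0.473, 0.385, 0.385, 0.351, 0.351 and 0.385 with an estimated correlation, and fry called 2 lists. The clock and insulin calls ended without surface control 1 (0.0503 for both), and the insulin call also without surface starved 1 (0.0788) or Tinaja starved 3 (0.0634).

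**Figure D3:**
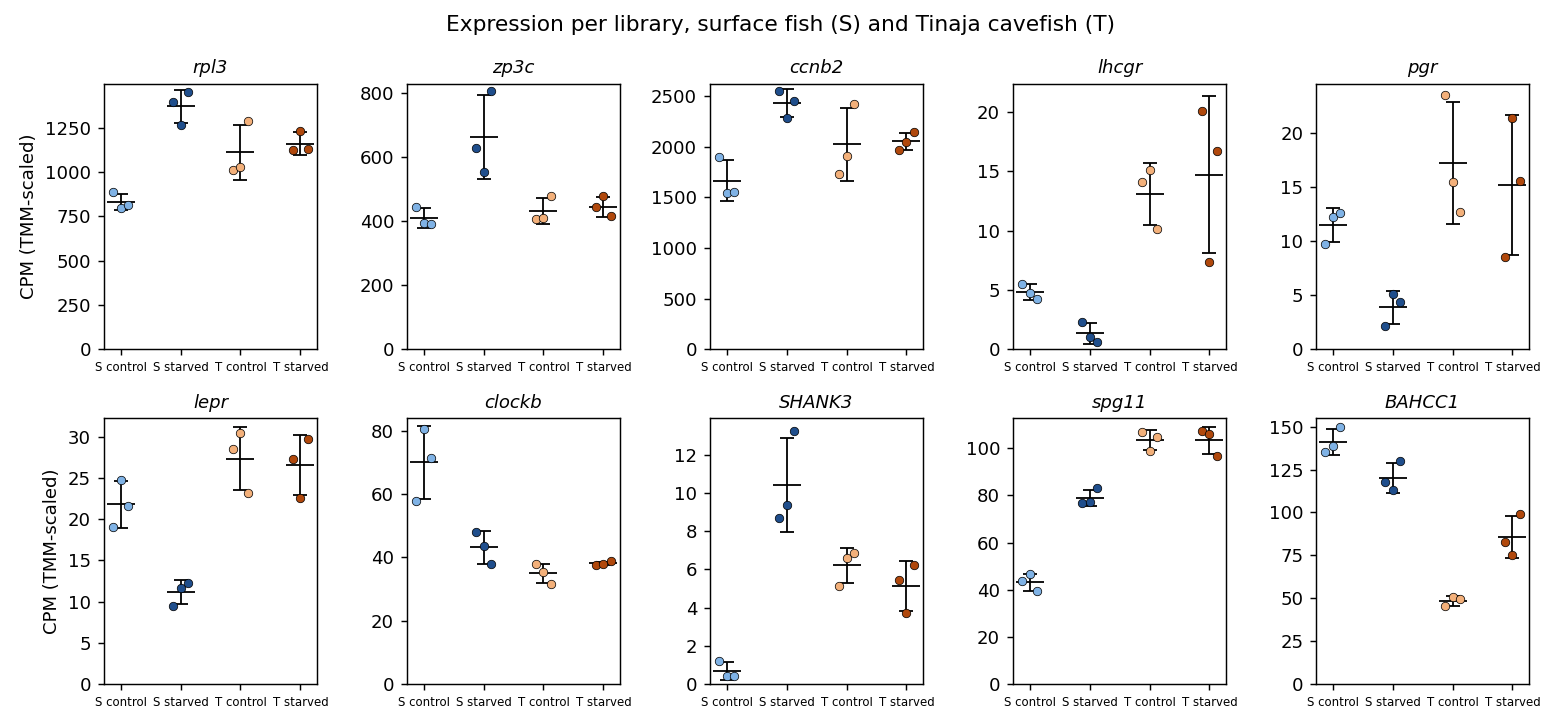
TMM-scaled CPM of 10 named genes in every library, with points for the 3 libraries of a group and bars for mean ± SD; S is surface fish and T Tinaja cavefish. In surface fish rpl3 goes from 832 to 1371 CPM and lepr from 21.8 to 11.1, and spg11 measures 43.2 and 78.9 CPM there against 103 in both Tinaja groups.

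Between control fish of the populations, genes of many kinds differed, some of them by presence or near absence of reads. Tinaja ovaries had 66.1 ± 26.1 CPM of clmnb, at least 505-fold more than surface ovaries with 0 reads. They had 11.2 ± 2.61 CPM of six7, a homeobox gene of cone photoreceptors (at least 85.8-fold), and 6.26 ± 0.899 of ODAD2, a gene of ciliary dynein arms (at least 47.9-fold). The cadherin gene cdh7a and selenoo2 had 1 read in all surface controls and ratios of 847 (95% counting interval 152 to 33500) and 470 (84.0 to 18600). Lower in Tinaja cavefish with 0 reads were lrit3a (65.7 ± 11.7 CPM in surface fish, at least 455-fold), cibar1 (at least 82.8-fold), the neurotrophin receptor gene NTRK2 (at least 70.3-fold) and ptprja (at least 70.0-fold). The gene ahsg2 had 1 read and a ratio of 786 (141 to 31100). The gene impdh1a was at least 44.6-fold higher and or70a15 at least 58.0-fold lower in Tinaja cavefish (adjusted p = 0.0270 and 0.0240). Both also varied between fish of 1 group. In starved surface fish or70a15 had 49, 0 and 0 reads, and in starved Tinaja cavefish impdh1a had 61, 0 and 44.

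Genes of the clock, steroid hormone and lipid lists were among those that differed between control fish. Of all tested genes 32.4% were called in this comparison, so calls in a list do not by themselves set it apart. In the clock list 10 of 33 were lower and 5 higher in Tinaja controls (11 and 5 adjusted over the list alone). The clock activator genes arntl2 and clockb measured 92.4 ± 5.43 and 69.9 ± 11.4 CPM in surface fish and 30.4 ± 1.35 and 34.9 ± 3.11 in Tinaja cavefish (adjusted p = 5.05e-07 and 0.000122). Steroid enzymes hsd17b12b and cyp17a1 were higher in Tinaja cavefish, at 17.2 ± 1.67 against 5.13 ± 1.22 and 4.46 ± 0.757 against 0.898 ± 0.584 CPM. In that list 4 of 14 genes were higher and 1 lower, the same adjusted over the list alone. The paralog hsd17b12a had far more reads than hsd17b12b. Before scaling they numbered 3362, 2744 and 3208 in surface and 2256, 2206 and 2648 in Tinaja controls, so the rise of hsd17b12b concerns the minor copy. In the ovulation list 7 of 19 were higher and 3 lower (9 and 3 adjusted over the list alone), with the prostaglandin synthase gene ptgs2a at 8.95 ± 4.77 against 0.176 ± 0.209 CPM. The desaturase gene scd was at 10.4 ± 2.67 against 0.404 ± 0.282 CPM and the peroxisomal thiolase gene acaa1 at 1.02 ± 0.150 against 11.5 ± 2.02. In the fatty acid synthesis list 4 of 22 were higher and 3 lower (4 and 5 adjusted over the list alone), and in the oxidation list 9 of 37 higher and 5 lower (10 and 5). The mitochondrial gluconeogenic gene pck2 was lower, at 62.3 ± 12 against 191 ± 36.2 CPM, and KLF15 higher, at 7.76 ± 1.96 against 0.958 ± 0.132. In the fasting response list 3 of 34 were higher and 3 lower, the same adjusted over the list alone. The log2 difference was 5.55 for ptgs2a (6.80 without surface control 2) and 4.65 for scd (5.24 without surface control 3). None of these lists was called by camera, with adjusted p of 0.509 for the clock, 0.12 for steroid synthesis, 0.114 for ovulation, 0.971 and 0.724 for fatty acid synthesis and oxidation and 0.739 for the fasting response.

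Single markers of other cell types were among the genes called. The smooth muscle myosin gene myh11a measured 44.4 ± 4.13 CPM in Tinaja and 7.35 ± 1.15 in surface controls, the fibronectin gene fn1b 63.9 ± 5.96 and 11.3 ± 3.51, and the leukocyte gene PTPRC 9.34 ± 2.23 and 1.11 ± 0.646. The collagen gene COL14A1 measured 1.85 ± 0.358 and 11.6 ± 2.29 and fgg, a fibrinogen gene expressed mainly in liver, 0.196 ± 0.169 and 9.51 ± 1.76. Of 31 stroma genes 7 were higher and 3 lower (8 and 3 adjusted over the list alone), of 15 smooth muscle genes 3 and 1 (3 and 1), and of 10 liver genes 0 and 3 (1 and 4). Their camera adjusted p was 0.0604, 0.388 and 0.391. The macrophage list, with 8 of 27 higher (8 adjusted over the list alone), and the ribosomal list, with 15 of 82 higher and 1 lower (8 and 1), were called by camera. RPS6KL1, which is no ribosomal protein, is 1 of these 15, at 13.5 ± 0.841 against 3.83 ± 1.07 CPM (adjusted p = 0.000101). The camera adjusted p was 0.0297 for both lists, and adjusted p = 0.872 with an estimated correlation. Both calls ended without surface control 2 (0.136), without surface control 3 (0.0876) and without Tinaja control 3 (0.0845 for macrophages and 0.350 for the ribosomal list), and the macrophage call also without Tinaja control 1 (0.116). The number of lists called was 4, 0 and 0 without surface control 1, 2 and 3, and 1, 6 and 0 without Tinaja control 1, 2 and 3.

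Key genes in control fish gave lhcgr at 13.1 ± 2.64 CPM in Tinaja and 4.85 ± 0.654 in surface fish (adjusted p = 0.0168) and bmp15 at 112 ± 3.04 and 133 ± 6.37 (0.0377). The lhcgr call ended without surface control 2 (0.0518) or 3 (0.0577) or Tinaja control 2 (0.0539). The bmp15 call ended without surface control 1 (0.112) or 2 (0.0757), without Tinaja control 1 (0.1), 2 (0.0803) or 3 (0.0596) and with upper-quartile factors (0.0828). Not called were gdf9 (0.0509), lepr (0.135), ddx4 (0.139), fshr (0.364), zar1 (0.402), insra (0.410), cpt1aa (0.587) and cyp19a1a (0.921). In total 4738 genes (32.4% of those tested) were called, 2344 higher and 2394 lower in Tinaja cavefish, and 2120 of them differed at least 2-fold (1156 higher, 964 lower). Of the 113 called genes named by rule, between 4 and 8 lost the call when any 1 library was left out, among them impdh1a without each library (up to 0.0638) and or70a15 without each Tinaja control (up to 0.0569).

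Between starved fish of the populations, genes of the egg coat, the oocyte, the ribosome and the follicle cells differed. Of all tested genes 40.3% were called there. Egg coat genes were lower for 8 of 9 members (8 adjusted over the list alone), with zpax1 at 742 ± 13.5 CPM in Tinaja and 1260 ± 35.9 in surface fish and zp2l2 at 549 ± 26.5 and 1020 ± 106. Genes of the ribosomal list were lower for 32 of 82 and higher for 2 (the same adjusted over the list alone). RPS6KL1, which is no ribosomal protein, is 1 of these 2, at 14.6 ± 2.45 against 4.44 ± 0.168 CPM (adjusted p = 0.000124). Among the lower were rpl6 at 403 ± 30.5 and 604 ± 44.7 CPM and rps9 at 169 ± 14.2 and 287 ± 26.5. Oocyte genes were lower for 11 of 23 (11 adjusted over the list alone), with bmb at 584 ± 26.3 and 752 ± 23.0 CPM and lhx8a at 91.4 ± 10.7 and 168 ± 8.01. Granulosa genes were higher for 6 of 10 (6 adjusted over the list alone), with lhcgr at 14.7 ± 6.62 and 1.34 ± 0.864 CPM and igf3 at 3.40 ± 1.85 and 0.514 ± 0.379. Steroid synthesis genes were higher for 8 of 14 and lower for 2 (10 and 2 adjusted over the list alone), with cyp17a1 at 4.61 ± 1.89 and 0.162 ± 0.0465 CPM. Without surface starved 1 the log2 differences of lhcgr and igf3 were 4.09 (3.47 with it) and 3.44 (2.71), and with thinned libraries that of cyp17a1 was 5.81 (4.66).

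These 5 lists were called by camera, with median log2 differences of -0.58 for the egg coat (adjusted p = 0.00449), -0.25 for the ribosomal list (8.56e-05) and -0.22 for the oocyte (0.0149). The medians were 2.26 for granulosa cells (0.0365) and 1.49 for steroid synthesis (0.0168). Lists of other cell types that camera did not call had medians of 1.64 for stroma (0.106), 1.43 for macrophages (0.226), 0.94 for smooth muscle (0.161), 0.89 for fat cells (0.448), 0.81 for blood vessels (0.480) and 0.55 for the epithelium (0.735), where camera's direction was lower. They were -1.31 for liver (0.0914), -0.98 for lymphocytes (0.448), -0.61 for red blood cells (0.448), -0.58 for skeletal muscle (0.421) and -0.29 for testis (0.448). Each of the 5 camera calls was lost, at adjusted p = 0.723 with an estimated correlation. The granulosa call ended without surface starved 1 (0.0559) or 2 (0.0610), without Tinaja starved 3 (0.0712) and with thinned libraries (0.0581). Of the stroma markers 12 of 31 were higher and 4 lower (12 and 4 adjusted over the list alone; camera adjusted p = 0.106), with fn1b at 32.9 ± 9.54 against 9.07 ± 2.7 CPM and COL14A1 at 2.12 ± 0.956 against 18.7 ± 2.62. The leptin receptor gene lepr measured 26.5 ± 3.63 CPM in Tinaja and 11.1 ± 1.45 in surface fish (adjusted p = 0.00014), and apaf1, which activates caspases, 41.3 ± 3.67 and 14.2 ± 2.57 (6.28e-06). The light-responsive gene cry5, a photolyase, was at 89.4 ± 5.28 against 52.8 ± 1.74 CPM, in a repair list with 3 of 15 higher and 1 lower (3 and 0 adjusted over the list alone; camera adjusted p = 0.804).

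In starved fish, six7 (at least 74.2-fold), matn1, a cartilage matrix protein gene (at least 53.7-fold), pip5k1bb (at least 46.7-fold) and GRIN2A, a glutamate receptor subunit gene (at least 44.5-fold), were higher in Tinaja cavefish against 0 reads. The genes clmnb (91.7 ± 14.7 against 0.261 ± 0.150 CPM) and tenm4, with 1 read in surface fish and a ratio of 657 (117 to 26000), were higher too. With voom tenm4 lost its call (0.0864). Reads of six7 numbered 131, 33 and 38 in the starved Tinaja libraries, so starved 1 weighs most in its bound. Control Tinaja cavefish had 25, 52 and 0 reads of matn1. Lower in Tinaja cavefish were col28a1a (at least 124-fold), plpp7a (at least 95.5-fold), and lrit3a with a ratio of 1910 (342 to 75500). So were ahsg2 (985, 176 to 38900), MFSD12 (732, 131 to 28900) and the cadherin gene CDH13 (0.224 ± 0.0520 against 135 ± 19.9 CPM). Control surface fish had 0, 41 and 56 reads of col28a1a. Among key genes, bmp15 (0.00347), gdf9 (0.00441) and zar1 (0.0321) were lower in Tinaja cavefish and cyp17a1 and lhcgr higher. The key genes insra (0.0707), cyp19a1a (0.139), fshr (0.149), ddx4 (0.238) and cpt1aa (0.482) were not called. The zar1 call ended without surface starved 1 (0.0645) or 3 (0.0947), without Tinaja starved 1 (0.113) or 3 (0.0647) and with upper-quartile factors (0.0569).

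In starved fish 5894 genes (40.3% of those tested) were called, 2963 higher and 2931 lower in Tinaja cavefish, and 2542 differed at least 2-fold (1531 higher, 1011 lower). Of the 129 called genes named by rule, 4 to 8 lost the call when any 1 library was left out. The 2 population comparisons share no library: 1605 genes were called higher in both and 1681 lower in both, where independent lists of these sizes would share 475 and 480, and 7 genes were called in opposite directions.

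**Figure D4:**
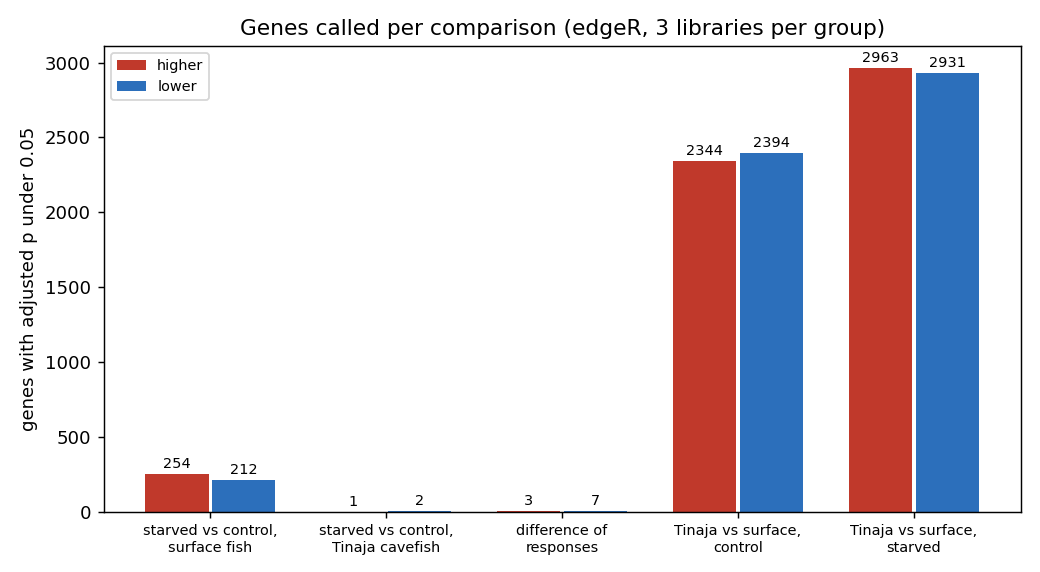
Number of genes called (adjusted p under 0.05, edgeR) as higher (red) or lower (blue) in each of the 5 comparisons, with 3 libraries per group. Starvation gave 254 higher and 212 lower genes in surface fish and 1 and 2 in Tinaja cavefish, and the populations differed by 2344 and 2394 genes in controls and 2963 and 2931 after starvation.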

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

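The tests of a cell share, of a response common to both populations, of mapping and of gene copies, and the thinning of libraries to equal depth, were chosen after the results were seen. The 10 genes given first were picked out because their starvation response differed between the populations by the test of that difference, and each value is the log2 response in Tinaja cavefish minus that in surface fish. ENSAMXG00000032655 gave -9.81 ± 0.414 (SE, edgeR adjusted p = 2.9e-06), with 0 reads in control and 13.8 ± 1.76 CPM in starved surface fish and 32.6 ± 2.34 and 30.0 ± 1.10 CPM in Tinaja cavefish. ENSAMXG00000031665 gave 5.3 ± 0.614 (0.00678), with 5.33 ± 1.10 and 0.260 ± 0.147 CPM in control and starved surface fish and 3.59 ± 0.897 and 7.11 ± 2.56 in Tinaja cavefish. ENSAMXG00000001654 gave -1 ± 0.117 (0.00678), with 81.1 ± 5.39 and 88.0 ± 0.315 CPM in surface fish against its fall in Tinaja cavefish. SHANK3 gave -4.17 ± 0.535 (0.0115; -4.90 without surface control 1) and spg11 -0.867 ± 0.111 (0.0115). ENSAMXG00000016415 gave -8.34 ± 0.996 (0.0129), with 16.5 ± 5.01 and 10.6 ± 4.58 CPM in surface fish. BAHCC1 gave 1.05 ± 0.141 (0.0129), PM20D2 -3.66 ± 0.522 (0.0192) and letm1 1.19 ± 0.169 (0.0192). ENSAMXG00000038070 gave -5.97 ± 0.841 (0.0383), with 0 reads in control and 0.781 ± 0.209 CPM in starved surface fish (at least 6.03-fold more) and 33.3 ± 9.02 and 25.5 ± 1.23 CPM in Tinaja cavefish. The fitted values of the genes with a group at 0 reads depend on the prior count and are no bounds. Their SE is derived from those values and does not measure how precisely the fold is known.

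Of 100 splits of the feeding labels within the populations, 13 called as many genes for the difference between responses as the real split (10 genes, highest other 569). For lists 13 of 100 splits called as many as the real 8 (highest other 13), so chance is not excluded for either count. The split with 569 genes kept the surface groups and set Tinaja control 3 and starved 2 and 3 against control 1, control 2 and starved 1. The other 6 drawn splits that kept the surface groups, the real one included, called 5 to 22 genes, and the Tinaja part alone called 5. Why the count of 569 arose was not tested. For each comparison of 3 against 3 libraries the 10 splits are too few for a share under 0.05. As many genes were called in 1 of 10 splits for starvation in surface fish (real 466, highest other 12) and in 6 of 10 in Tinaja cavefish (3 and 78). The same held in 1 of 10 between populations in controls (4738 and 1) and 1 of 10 after starvation (5894 and 0). As many lists were called in 3, 8, 9 and 3 of 10 splits in that order, with real numbers of 6, 2, 2 and 5 and highest others of 6, 14, 9 and 8. The Tinaja split with 78 genes set control 1 and starved 2 and 3 against control 2, control 3 and starved 1. These are the sides of the second principal component, which points to a structure of these samples other than feeding. So does the split with 14 lists, several times the real 2, which set control 1, control 3 and starved 2 against control 2, starved 1 and starved 3. The former 3 had higher mean levels of the macrophage, stroma, fat cell and epithelium lists than each of the latter 3. Between populations in controls, the split with 9 lists set surface control 1 and Tinaja control 1 and 3 against the others, and also called several times the real 2.

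The first pattern weighed is the rise of the oocyte and ribosomal lists and the fall of the granulosa list in starved surface fish, by camera at the preset correlation. Tables argue against greater depth of the starved libraries as the whole cause: thinned to equal gene reads, 423 genes were called against 466, and the list medians were 0.286, 0.409 and -1.42 against 0.298, 0.386 and -1.56. A lower share of follicle and stromal cells of every kind alike may contribute and stays open. It predicts equal falls of the cell type lists, and the granulosa list fell by 0.651 more than the stroma list on the log2 scale (-0.651, SE 0.247), without overlap of the 3 control and 3 starved libraries, which chance gives in 10% of cases. The granulosa genes lie near the floor, with a median of 1.69 CPM, under 10 times the 0.393 CPM of 3 counts (stroma 4.23 CPM), so the gap does not decide, and starvation itself, which the design names, also stays open.

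The second pattern is the set of genes nearly on or off between control and starved fish, weighed on the 88 surface genes called with at least 2-fold change. A response common to both populations is argued against by a median Tinaja change of 0.0347 on the log2 scale signed by the surface direction (quartiles -0.207 to 0.219), against 1.91 in surface fish, with 49 of 88 (55.7%) of the same sign. Different haplotypes in control and starved fish might also give such genes, and would place them next to each other on the genome. There were 2 pairs within 10 gene positions, against a median of 1 in random sets of as many genes (permutation p = 0.457). As 38 of the 88 genes (43.2%) could be placed by symbol, this test is void, and haplotypes and a response of surface fish cannot be told apart here.

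The third pattern is the set of genes detected in 1 population at 5 CPM or more and near 0 (at most 3 counts) in the other. A poorer mapping of all reads of 1 population, as the whole cause, is argued against by similar numbers, 45 genes near 0 in surface fish and 36 in Tinaja cavefish, a ratio of 1.25. Unmapped reads were 8.74% ± 1.00 and 9.04% ± 1.11 of reads. Reads mapped to several places were 12.3% and 10.7% in control and starved surface fish, and 12.9% and 14.2% in Tinaja cavefish. Those outside any annotated gene were 16.4% and 15.0% in surface fish, and 17.2% in both Tinaja groups. What this does to single genes was not tested. Reads counted to another copy of the gene could contribute to single cases: 5 of 57 such genes with a symbol (8.77%) share it with another tested gene, against 6.58% of 11411 others (Fisher's exact test, two-sided, p = 0.424). A further 24 have no symbol, so copies stay open, as do sequence variants against the reference and a biological difference between the populations, both untested. Some genes named above also varied between fish of 1 population, such as or70a15 with 49, 0 and 0 reads in starved surface fish.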

How the results depend on the processing

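The thinned libraries, the recovered reads and the ribosomal list without RPS6KL1 were chosen after the data were seen, and all other alternatives before. The cause of a change was not tested unless stated. For starvation in surface fish (466 genes), a minimum of 2-fold left 88 by construction, DESeq2 called 1304 (462 shared with the 466), the fit of the 6 libraries alone 141 (113 shared) and fits without 1 library 27 to 540. In simulations with known answers 17.1% of the DESeq2 calls for this comparison were false, against 3.01% of those of edgeR. These simulations held no structure of the samples beyond the changed genes and took the spread from edgeR. They do not settle which tool has more false calls in the real data. Counts with relative log expression or upper-quartile factors, voom, no low-count filter, the 10 CPM filter, thinned libraries and recovered reads ranged from 329 to 664. The share of higher calls was 54.5%, and 46.2% with upper-quartile and 57.1% with relative log expression factors. For starvation in Tinaja cavefish (3 genes) the 2-fold minimum left 1, DESeq2 called 20, the fit of the 6 libraries alone 0 (452 at an unadjusted p under 0.05) and fits without 1 library 3 to 34. Other alternatives gave 3 or 4. For the difference between responses (10 genes) DESeq2 called 255 and fits without 1 library 8 to 49, and others 7 to 11. Between populations, the 2-fold minimum left 2120 of 4738 genes in controls and 2542 of 5894 after starvation. All other settings gave 3653 to 5008 and 4414 to 6154. For the shared starvation response DESeq2 called 2 genes against 0 by edgeR.

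With a correlation estimated per list, camera called 0 lists in each of the 5 comparisons, against 6, 2, 8, 2 and 5. Lists at an unadjusted p under 0.05 then numbered 3, 5, 4, 1 and 2. The rotation test fry, which does not compare a list with other genes, called 12, 0, 2, 6 and 18. Fits without 1 library called 6 to 9, 1 to 13, 7 to 11, 0 to 6 and 4 to 7 lists. Numbers under relative log expression factors, thinned libraries and without RPS6KL1 differed by at most 1 list.

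This part covers the genes named by rule, and some known only by an identifier and named after their values were seen. Among results called in the main fit or in the alternative, 0 reversed direction under any alternative. A change of sign in a result called in neither was not counted. In the fits without 1 library each result was counted once per library left out. The call ended in 214 of these cases and was made in 5, with 1851 on the same side. Other alternatives counted each result once, so their numbers cannot be set beside these. The numbers ended and made were 28 and 2 in fits of the groups compared alone, 18 and 2 with voom and 10 and 0 with thinned libraries. They were 8 and 0 without the low-count filter, 8 and 0 with upper-quartile factors and 2 and 2 with DESeq2. With relative log expression factors and the 10 CPM filter 0 changed side by edgeR.

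With the replicate number as a block, 80 genes were called for starvation in surface fish (78 shared with the 466), 3 in Tinaja cavefish, 10 for the difference between responses, 4377 and 5430 between populations and 0 in both starvation responses. Of the named results 28 lost their call under the block and 1 gained one, and the numbers of lists called were the same. The numbers do not pair the libraries: 18 pairs with the same number had a median correlation of -0.0228 of their deviations from the group means (-0.311 to 0.0826, 0 above 0.1). The 36 other pairs had a median of 0.0138 (highest 0.303, 3 above 0.1).

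What depth limits was not tested by level of expression. In each library 3 counts equal 0.323 to 0.491 CPM. In simulations, which changed better counted genes only, 32.8% of genes changed 1.5-fold were recovered for starvation in surface fish and 37.3% in Tinaja cavefish.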

Other observations

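The lists and tests in this part were all fixed before the results were seen. Some genes of meiosis were called between control fish of the populations, where 32.4% of all tested genes were. The gene spo11, which makes the DNA breaks that start meiotic recombination, measured 43.2 ± 5.99 CPM in Tinaja and 4.22 ± 2.76 in surface fish (n = 3 each, edgeR adjusted p = 0.00224). Its log2 difference was 3.36, and 3.98 without surface control 3. The gene mnd1 was lower in Tinaja cavefish (18.8 ± 5.54 against 34.1 ± 4.42, 0.00656). Of 16 genes of that list 5 were higher and 4 lower (6 and 4 adjusted over the list alone; camera adjusted p = 0.739). Among antioxidant genes, the thioredoxin reductase gene txnrd3 was at 56.5 ± 0.317 CPM in Tinaja and 121 ± 11.3 in surface controls (3.3e-06), and prdx4, a peroxiredoxin, at 47.6 ± 2.94 and 28.7 ± 2.26 (0.000234). Of 33 such genes 7 were higher and 6 lower, the same adjusted over the list alone (camera adjusted p = 0.971). Nuclear genes of oxidative phosphorylation were higher for 23 of 84 and lower for 9, the same adjusted over the list alone (camera adjusted p = 0.114), with ndufc1 at 30.5 ± 2.32 against 11.9 ± 1.15 CPM (3.52e-05). The mitochondrial folate enzyme gene mthfd2 was lower, at 13.9 ± 1.33 against 40.3 ± 8.13 CPM (5.58e-05), in a stress response list with 4 of 31 higher and 4 lower, the same adjusted over the list alone (0.739).

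Between starved fish 40.3% of all tested genes were called, among them some genes of nutrient signalling. The kinase gene mtor measured 269 ± 4.35 CPM in Tinaja and 349 ± 26.1 in surface fish (adjusted p = 0.000629), and the receptor genes igf1ra 14.1 ± 2.31 and 5.63 ± 1.31 (0.00153) and ghrb 24.4 ± 2.44 and 14.9 ± 0.918 (0.00271). Of 31 genes of insulin, IGF and mTOR signalling 9 were higher and 2 lower in Tinaja cavefish, the same adjusted over the list alone (camera adjusted p = 0.241). The glucose-responsive factor gene MLXIPL was at 6.89 ± 2.56 against 0.566 ± 0.175 CPM (9.93e-05) and txnipb at 14.0 ± 1.66 against 105 ± 6.25 (0.000442). Among autophagy genes, the kinase gene ULK2 was at 33.4 ± 4.42 against 13.9 ± 1.17 CPM (0.000242) and wipi1 at 0.944 ± 0.374 against 5.42 ± 0.790 (0.000607), with 9 of 59 higher and 11 lower, the same adjusted over the list alone (0.608). The unfolded protein response factor xbp1 was at 7.39 ± 2.71 against 1.23 ± 0.592 CPM (0.000682), in a folding list with 8 of 25 higher and 8 lower, the same adjusted over the list alone (0.896). Cell cycle genes were lower for 13 of 40 and higher for 1, the same adjusted over the list alone (0.0914), with cenpe at 929 ± 49.9 against 1457 ± 23.2 CPM (0.000263).

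Between controls of the populations, yolk uptake had 2 of 11 higher and 2 lower, cholesterol synthesis 3 of 29 and 8, lymphocytes 1 of 6 and 2, complement 2 of 18 and 4, red blood cells 1 of 11 and 3 and skeletal muscle 2 of 10 and 3. Immediate early genes had 0 of 15 and 2, the ovarian surface epithelium 0 of 9 and 2, pigment and cave-trait genes 2 of 9 and 1, fat cells 1 of 11 and 0, testis 0 of 5 and 1 and apoptosis 3 of 22 and 6. Adjusted over the list alone the numbers were 2 and 2, 3 and 8, 2 and 2, 3 and 4, 1 and 4, 2 and 3, 0 and 2, 0 and 2, 2 and 1, 0 and 0, 0 and 1, and 4 and 6. The camera adjusted p of these lists was 0.0553 or more in each of the 5 comparisons.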
